A study of Mus musculus with 6 samples.

How the data were processed

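Total RNA from mouse embryonic stem (ES) cells was labelled with Cy3 and hybridised to 1-colour Agilent oligonucleotide arrays, 1 array per culture. The labels describe cells kept undifferentiated with leukemia inhibitory factor on a layer of mitomycin-inactivated mouse embryonic fibroblasts, and they name 3 wild type and 3 Zscan5b knockout samples as biological replicates. Each sample was placed in its group by its title. The labels do not say where the deletion lies, how the knockout was made, or whether the knockout replicates came from separate clones.

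The deposited scanner tables hold spot intensity on a linear scale. Per the file headers, Feature Extraction 10.7.3.1 subtracted the background by a spatial detrend, applied a multiplicative detrend and replaced signals not above background by a surrogate value. The submitters' processing notes name version 10.3.1.1 of the same program, and the difference between the 2 versions was not resolved. The authors' series table holds log2 values. For comparison the log2 scanner values were centred per probe. Against those of the same array the authors' values had a slope near 1 and r from 0.986 to 0.996 across probes, which are not independent replicates. In the authors' table each probe's median over the arrays lay at 0 (largest deviation 0.005). The column medians of that table were 0.02, -0.01 and -0.07 for wild type replicates 1 to 3 and -0.02, 0.02 and 0.03 for the knockout replicates, and the exact scaling of its columns is not given in the sources used here. It served as an alternative.

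For the main values, control spots and spots marked as outliers were left out, the processed signal was taken as log2, replicate spots of a probe were averaged, and each array's 75th percentile was subtracted. The arrays carried 39429 gene probes on 43020 spots. A probe was tested where it was well above background on at least 3 of the 6 arrays, which left 26651 probes (67.6%). Groups were compared with lmFit and eBayes in limma 3.58.1 under R 4.3.3 (two-sided), with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. The R package data.table (version 1.17.8) read the tables. The replicate number was not used as a block. A log2 fold change is always knockout minus wild type. Where every array of the dimmer group was not well above background, the fold is a bound: the brighter group's mean against the dimmer group's mean of, per array, the higher of the probe's own signal and the lowest signal well above background. No probe was saturated.

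Probe positions are those in the scanner files, on the mouse build mm9. Gene names were updated through a table of RefSeq genes on assembly GRCm38.p6, used for names only. Of the gene probes, 26761 were named by accession, 3814 already carried a current symbol, 639 matched a synonym, 5509 kept the file's name and 2706 had no name. Where a gene had several probes, its representative was the tested probe with the highest mean over all 6 arrays, and disagreement between probes is stated.

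Gene lists were tested with limma's camera on 1 probe per gene (18970 genes), with a preset inter-gene correlation of 0.01 and again with an estimated correlation, and with Benjamini-Hochberg adjustment over the 27 lists. They covered core, naive and primed pluripotency, two-cell and zygotic genome activation genes, SCAN domain zinc finger genes, homologous recombination and DNA damage repair, p53 target genes, mitosis, G1/S and DNA replication, linker and core histones, RNA polymerase III, endoderm, mesoderm, neuroectoderm, trophoblast, germline, imprinted, Y-linked and X inactivation genes, feeder fibroblast markers, interferon response, glycolysis and hypoxia, cholesterol synthesis, the integrated stress and unfolded protein response, immediate early and heat shock genes, and DNA methylation and repressive chromatin. Each list's mean per array was also compared by an exact two-sided permutation test, whose smallest possible p with 3 against 3 arrays is 0.1. Chromosomes were tested in the same way as lists, and probes within 1 Mb of Zscan5b were counted separately.

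The lists, tests, first set of processing choices and the rule for named genes were fixed before the data were examined. The rule named Zscan5b, then in each direction the 10 genes with the largest fold change among representative probes that passed the test, separated the groups completely and were well above background on every array of the brighter group, leaving out clone, predicted and accession names. From each list it took up to 4 members with the smallest p that passed the test over all probes, or up to 2 members, given as values, where none passed. Of the genes that this rule takes, 2 are not reported here. Other named genes were chosen after their values were seen, as stated beside them.

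On simulated data with the real probe means and spreads, 83 of 100 probes changed by log2 2 and 43 of 100 changed by log2 1 were called, with 7 false calls among 26394 unchanged probes. A list shifted by 0.5 was called and no list was called without a shift. The simulated genes varied independently of each other, and the simulation held no difference between slides. These counts therefore do not measure how many probes or lists are rightly or falsely called on the real arrays. Groupings of the real arrays that mix the genotypes called 4 to 10 lists. The alternatives tried were quantile normalization, a shift to the median of the tested probes, normexp background correction (offset 50), the authors' log2 values, no detection filter, detection on all 6 arrays, a trended and robust variance prior, array weights, a replicate block, leaving out each array in turn, stricter thresholds, an estimated correlation and the mean over a gene's probes. Testing only the probes with signal above the median of the tested probes was added after seeing the data.

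The wild type arrays lay on slide 1 of scan 1 and the knockout arrays on slide 2 of scan 2, so batch and group cannot be told apart, and a planned fit with the slide as a block could not be made. The limma p-values of single probes measure the spread between these 6 samples, and no p-value here covers the spread between slides. The camera p-values with the preset correlation rest largely on the spread between genes, taken as nearly independent. With 3 arrays per group, their number limits the precision.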

Results

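Gene expression was measured in wild type mouse ES cells and in ES cells with a knockout of Zscan5b, which encodes a zinc finger protein with a SCAN domain. The series compares the genotypes directly, with 3 arrays in each group. Among 39429 gene probes, 26511, 27754 and 27161 were well above background in wild type replicates 1, 2 and 3, and 27111, 25487 and 25371 in knockout replicates 1, 2 and 3. The 75th percentile of signal lay between 852 and 1028 on all 6 arrays. The knockout arrays resembled each other more closely than the wild type arrays did. The SD of the log2 difference between 2 arrays was 0.33 to 0.40 within the knockout, 0.51 to 0.64 within wild type and 0.49 to 0.70 between genotypes. Each genotype occupied its own slide and scan, so batch and group cannot be told apart in any result that follows.

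Zscan5b itself read lower in the knockout arrays, by 2.498-fold (log2 fold change -1.32 ± 0.29, SE, n = 3 per group), but it missed the threshold, with a limma adjusted p of 0.107. Its only probe (A_55_P2419141, mm9 chromosome 7, 6190808 to 6190867) read -3.66, -4.03 and -3.12 in wild type and -4.47, -5.17 and -5.13 in the knockout, as log2 signal relative to each array's 75th percentile. All 3 knockout values lay below all 3 wild type values, and the probe remained well above background on all 6 arrays. The labels do not place the deletion, and a probe outside the deleted part checks nothing about the genotype. The Zscan5b log2 fold change passed with array weights (-1.58, adjusted p 0.0448) and without wild type replicate 2 (-1.54, adjusted p 0.0416), and it was -0.59 under normexp background correction, with adjusted p from 0.0416 to 0.346 over the alternatives. Normexp was run with an offset of 50 added to every signal, which shrinks the fold of a dim probe by construction.

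Egln1, Ndufa4l2, Pfkfb3 and Xlr5a were among the genes that rose in the knockout. Egln1, a prolyl hydroxylase that marks hypoxia-inducible factors for degradation in normal oxygen, rose by a log2 fold change of 1.47 ± 0.10 (SE, n = 3 per group), from -4.66 ± 0.04 in wild type to -3.19 ± 0.09 (SD, n = 3). Ndufa4l2, a mitochondrial protein induced in hypoxia, rose by 1.56 ± 0.20 (probe on mm9 chromosome 10, 126954149 to 126954208), and Pfkfb3, which makes the activator of phosphofructokinase, rose by 1.11 ± 0.14 (chromosome 2, 11393453 to 11393512). Tfrc, the transferrin receptor, rose by 1.03 ± 0.12 (chromosome 16, 32632255 to 32632314). Another Tfrc probe also passed (1.18), and the third (0.98) did not, with an adjusted p of 0.0839. The highest log2 fold change among the higher genes named by the fixed rule was that of Xlr5a, an X-linked gene of a lymphocyte-regulated family with closely related copies that 1 probe may not tell apart, at 1.88 ± 0.18 (chromosome X, 70352978 to 70353037). H2-Ab1, a chain of the MHC class II molecule, rose by 1.25 ± 0.12, with 1.21 at its other probe. Krt20, an epithelial keratin, rose by 1.18 ± 0.14, and Pvr, the poliovirus receptor homologue, by 1.13 ± 0.12. Fsd1l rose by 1.30 ± 0.15 at its representative probe, whereas its other probes read 0.30 and -0.51 and were not called. The adjusted p of these 9 genes lay between 0.0374 and 0.0478, and in each of them all 3 knockout arrays exceeded all 3 wild type arrays. Under normexp background correction, where none was called, the log2 fold change of Egln1 was 0.66 and that of Krt20 0.76. The added offset shrinks the folds of such dim probes. Among genes chosen after their values were seen, Hjurp, the chaperone that deposits the centromeric histone CENP-A, rose at 3 of its 4 probes (0.93, 0.90 and 0.83), and Id2, an inhibitor of basic helix-loop-helix transcription factors, rose by 0.96.

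The genes that fell included Tnfsf11, Stfa3, Tac1 and several olfactory receptors, and their probes were dim. Tnfsf11, which encodes the cytokine RANKL, fell by 2.34 ± 0.26 on the log2 scale (SE, n = 3 per group, adjusted p 0.0377), and 1 of 3 knockout arrays still read it well above background. The other 9 named genes were not well above background on any knockout array, so only a bound can be given. Stfa3, a stefin, was at least 3.11-fold lower, and the olfactory receptors Olfr353, Olfr1221 and Olfr661 were at least 2.75-fold, 2.195-fold and 1.73-fold lower. Fpr-rs3, a formyl peptide receptor found in vomeronasal neurons, was at least 2.01-fold lower. Dynap was at least 1.502-fold lower, Tac1, the precursor of substance P, at least 1.41-fold, Ttc23l at least 1.35-fold and Gabra3, a GABA receptor subunit, at least 1.34-fold. The limma adjusted p of all 10 genes lay between 0.0374 and 0.0485, with every knockout array below every wild type array. For the 9 genes with a bound, limma used knockout signals that were not well above background. Dynap, for instance, was fitted at -2.76 ± 0.26 on the log2 scale. The adjusted p therefore tests the fitted values and does not test the bounds. Under normexp, where none was called, the fitted log2 fold change of Tnfsf11 was -0.89, and those of the other 9 genes lay between -0.59 (Stfa3) and -0.25 (Tac1), smaller than their bounds. The offset of 50 added there shrinks the folds of dim probes by construction, so these smaller values do not speak against the bounds.

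In all, 124 of 26651 probes passed the limma test, 33 higher and 91 lower in the knockout. By representative probe these were 17 higher and 70 lower genes. At least a 2-fold change was fitted for 18 of the higher and 70 of the lower probes, although 41 of the lower probes were not well above background on any knockout array. The lower calls were concentrated near the detection limit: 89 of 91 came from the dimmest 40% of the tested probes and 0 from the brighter part above the median, against 14 of 33 higher calls in each. The smallest adjusted p was 0.0288, and 5836 probes had an unadjusted p below 0.05, where independent probes would give 1333 by chance and another grouping of the same arrays gave 4189. The groups did not overlap in 7735 probes (29.1%, where chance gives 10%). No probe was called in either direction under normexp background correction, without a detection filter, with detection required on all 6 arrays or with a trended and robust variance prior, while 434 were higher and 406 lower with array weights and 54 and 177 under a shift to the median. Wild type replicate 2 reduced the calls, which numbered 1409 higher and 1148 lower without it, and 203 and 437 without wild type replicate 1, whereas 0 remained without wild type replicate 3 or without knockout replicate 1, 2 or 3.

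**Figure D1:**
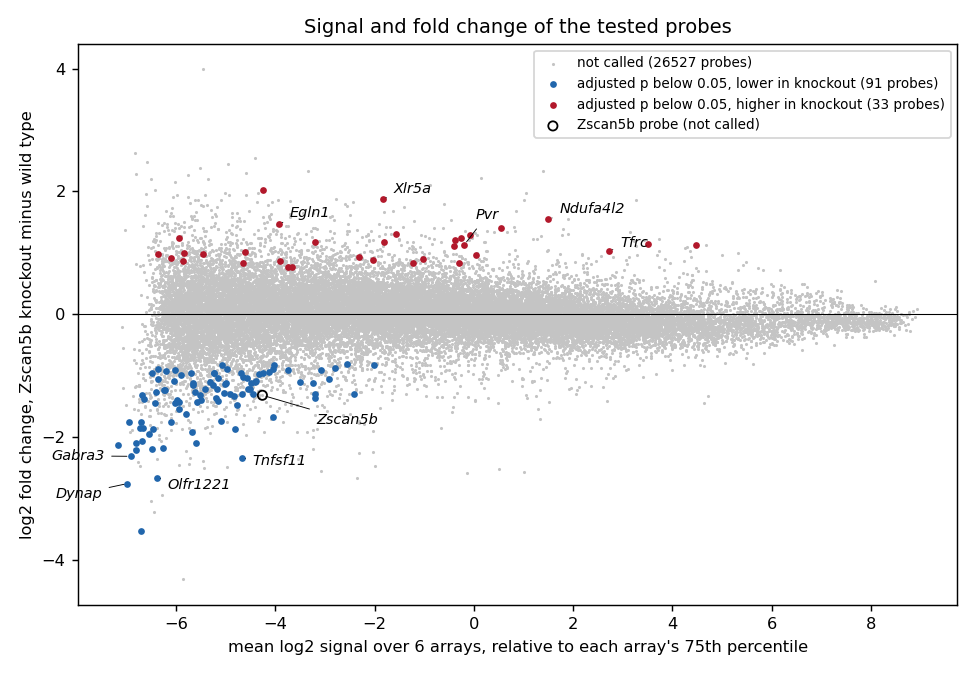
Log2 fold change (knockout minus wild type, vertical axis) of each tested probe against its mean log2 signal over the 6 arrays relative to the array's 75th percentile (horizontal axis), with the 33 higher calls in red, the 91 lower calls in blue and probes that were not called in grey. The lower calls sit at the dim end, the higher calls extend to bright probes, and the Zscan5b probe (open circle) at -1.32 is not called.

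Glycolysis and hypoxia genes shifted upward together in the knockout. Of the 35 members measured, 30 had a positive and 5 a negative log2 fold change, with a median of 0.52, and the camera adjusted p was 1.63e-09. With an estimated correlation between genes the adjusted p was 0.709 and the unadjusted p 0.0609, so the call did not hold there. Over all probes tested, 1 member was higher (Egln1), 0 were lower and 34 were not called. When adjusted over the list alone, 17 were higher and 1 was lower. The higher members included Aldoc (1.11 ± 0.18, SE) and Pfkl (1.04 ± 0.20), enzymes of glycolysis, and Ndrg1 (1.23 ± 0.23), a hypoxia-inducible gene. The member that was lower over the list alone was Hif1a itself, at -0.37 ± 0.11, whose dimmer probe read 0.87 (these 4 genes were chosen after their values were seen). The list mean was -0.26 ± 0.07 in wild type and 0.26 ± 0.12 in the knockout (SD, n = 3, centred log2 signal), and all knockout arrays exceeded all wild type arrays, with an exact permutation p of 0.1, the smallest this design allows. Markers of feeder fibroblasts differed between the same groups in the other direction, with a median of -0.83.

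Target genes of the tumour suppressor p53 were also called higher as a list. Of 30 measured members, 24 were positive and the median was 0.24, with a camera adjusted p of 0.00191 (adjusted p 0.709 with an estimated correlation). With the 6 arrays regrouped so that the genotypes mix, the same camera test called 4 to 10 lists, against 5 in the real grouping. The mixed groupings do not balance the genotypes, so part of any difference between the genotypes remains in them. They cannot show how many lists are called by chance, but a list call of this kind does not by itself point to the genotype. By representative probe no member was called over all probes by limma, and 6 higher and 1 lower had an unadjusted p below 0.05. That is near the rate over all tested probes, 5836 of 26651. Adjusted over the list alone, 3 were higher and 0 lower: Gadd45b (1.29 ± 0.26, SE), a stress-inducible growth arrest gene, Btg2 (0.77 ± 0.16), an antiproliferative gene, and Ddit4 (0.96 ± 0.22), an inhibitor of mTOR signalling that is also induced in hypoxia. Cdkn1a, the cell cycle inhibitor p21 and a gene chosen here after its values were seen, rose by 2.02 ± 0.23 at 1 dim probe that was called, while its brighter probes read 0.50 and 0.43 and were not called. The list mean was higher in the knockout with an exact permutation p of 0.2, because wild type replicate 2 (0.10) lay above knockout replicate 1 (0.07).

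The mitosis and spindle checkpoint list moved by a small amount in the same direction. Its 48 members had a median of 0.078, with 33 positive and 15 negative, and a camera adjusted p of 0.0336 (adjusted p 0.709 with an estimated correlation). By representative probe no member was called over all probes by limma or when adjusted over the list alone. An unadjusted p below 0.05 was found for 7 higher and 1 lower, no more than the rate over all tested probes (5836 of 26651). Another probe of Cdk1, a mitotic kinase and a gene chosen here after its values were seen, was called (0.88), while its brightest probe read 0.12 and its dimmest -0.31. Cenpf, a kinetochore protein, read 0.61 ± 0.15 and Anln, a scaffold of the cytokinetic ring, 0.38 ± 0.10. The exact permutation p of the list mean was 0.1. The median was 0.18 under quantile normalization and 0.050 under normexp, where the list stayed called, and adjusted p ran from 3.17e-05 to 0.709 over the alternatives. The call was lost under a shift to the median of the tested probes (median 0.023, adjusted p 0.0798), without a filter (0.151) or with detection on all 6 arrays (0.0567), and without wild type replicate 2 (0.0565), wild type replicate 3 (0.0567), knockout replicate 1 (0.0512) or knockout replicate 3 (0.0684).

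Markers of the feeder fibroblasts were lower on average in the knockout arrays, but they varied more among the wild type arrays. Of 37 measured members, 34 were negative, with a median of -0.83 and a camera adjusted p of 3.09e-04 (adjusted p 0.709 with an estimated correlation). No member was called over all probes by limma or when adjusted over the list alone. An unadjusted p below 0.05 was found for 1 higher and 11 lower, against 5836 of 26651 over all tested probes. Serpinh1, a collagen chaperone, read -0.65 ± 0.13 and Vim, an intermediate filament, -0.74 ± 0.18. The list mean was -0.53 in wild type replicate 1 against 0.93 and 0.82 in replicates 2 and 3, and -0.55, -0.18 and -0.49 in the knockout. The exact permutation p was 0.3. Without wild type replicate 1 the median was -1.34, and without wild type replicate 2 it was -0.55 and the list was no longer called (adjusted p 0.0568, from 6.17e-17 to 0.709 over the alternatives).

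Two-cell and zygotic genome activation genes, which are switched on in the early embryo and in rare ES cells, showed the opposite arrangement. Of 18 measured members, 15 were positive, with a median of 0.90 and a camera adjusted p of 0.0336 (adjusted p 0.709 with an estimated correlation). No member was called over all probes, none passed when adjusted over the list alone, and 0 had an unadjusted p below 0.05 in limma. Usp17la and Usp17ld, deubiquitinase genes with closely related copies, read 0.48 ± 0.20 and 0.24 ± 0.11, and the Zscan4 genes, also a cluster of related copies and chosen after their values were seen, read from 0.79 (Zscan4c) to 0.99 (Zscan4e). The list mean was 0.66 in wild type replicate 1 against -0.98 and -0.75 in replicates 2 and 3, and 0.44, 0.15 and 0.49 in the knockout, with an exact permutation p of 0.4. The median was 1.67 without wild type replicate 1, where it stayed called, and 0.29 without wild type replicate 2, where it was not (adjusted p 0.241, from 9.44e-08 to 0.709 over the alternatives). It was 0.40 under normexp, still called. It was also not called without wild type replicate 3 (0.0599), knockout replicate 1 (0.0683) or knockout replicate 3 (0.0698), under quantile normalization (0.0617), with detection on all 6 arrays (0.105) or with array weights (0.104).

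**Figure D2:**
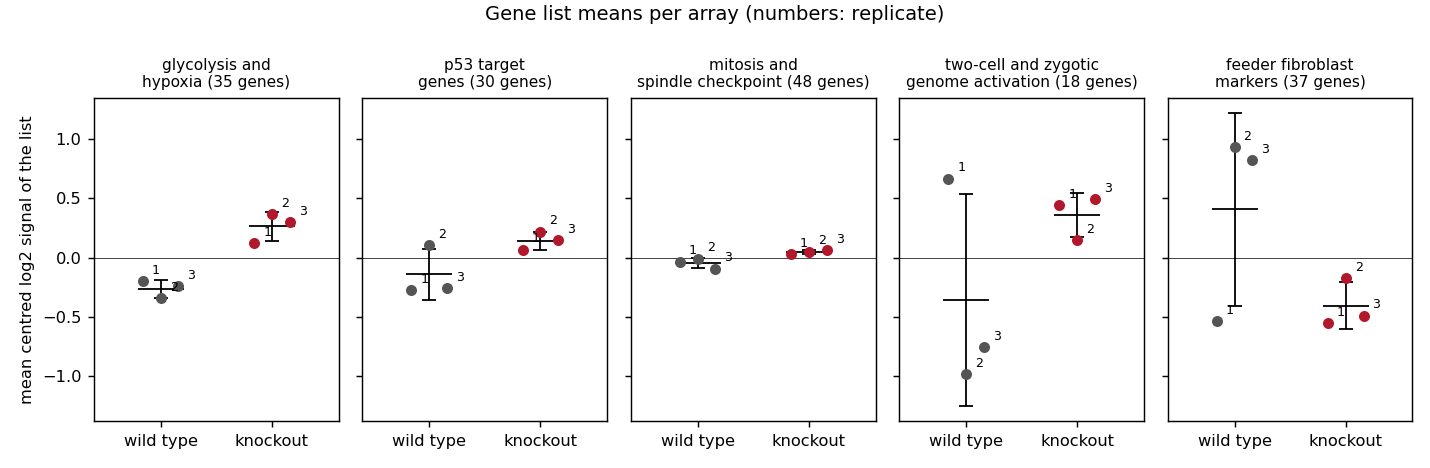
Mean centred log2 signal of 5 gene lists on each array (points, numbered by replicate) for wild type (grey) and Zscan5b knockout (red), with the group mean and SD (bars). The glycolysis and hypoxia list and, by less, the mitosis and spindle checkpoint list separate the genotypes, which lay on separate slides. In the feeder and two-cell lists wild type replicate 1 (-0.53 and 0.66) lies with the knockout arrays, apart from replicates 2 and 3.

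The other 22 lists did not pass, with camera adjusted p from 0.0561 to 0.971. Of their 597 member entries, 0 were called higher by limma, 1 was called lower and 596 were not called. At an unadjusted p below 0.05 there were 59 higher and 78 lower, near the rate over all tested probes (5836 of 26651). In at least 1 alternative 9 of these lists passed, and in 7 the median changed sign (SCAN domain, Y-linked, germline, imprinted, interferon response, linker histone and endoderm genes). Pluripotency genes were among those without a call. The core list (24 tested) had a median of -0.29 and an adjusted p of 0.179, with the stem cell transcription factors Pou5f1 at -0.47 ± 0.10 and Nanog at 0.66 ± 0.22, and it was called lower without wild type replicate 2 (median -0.45, adjusted p 0.00701, up to 0.709 over the alternatives). The naive list (26 tested, adjusted p 0.213) had 1 member higher when adjusted over the list alone, Pecam1 (0.47 ± 0.09), beside Spp1 at -1.02 ± 0.26. The primed list (21 tested, adjusted p 0.169) held Grhl2 at -0.77 ± 0.19 and Etv5 at -0.65 ± 0.17, with a median of -0.17. It was called lower without wild type replicate 2 (median -0.55, adjusted p 0.00189) and with array weights (-0.39, 0.0322), and its adjusted p ran up to 0.998 over the alternatives. DNA methylation and repressive chromatin genes (33 tested, adjusted p 0.169) included the methyltransferase Dnmt3b at -1.44 ± 0.42 and the remodeller Hells at -0.51 ± 0.14, and were called lower without a filter (adjusted p 0.0429) and without wild type replicate 2 (0.0322).

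Lineage markers did not pass either. Neuroectoderm genes (24 tested, adjusted p 0.0968) had 4 members higher and 2 lower when adjusted over the list alone, with Olig2 at -0.58 ± 0.12 and Six3, well above background on 2 wild type arrays and 1 knockout array, at 0.47 ± 0.11. They were called higher without wild type replicate 3 (adjusted p 0.0262), without knockout replicate 2 (0.0401) and with the mean over a gene's probes (median 0.39 against 0.21, adjusted p 0.0209). Endoderm genes (25 tested, adjusted p 0.196) had 1 lower over the list alone, Sox7 (-1.25 ± 0.22). Dab2, a further endoderm gene outside those 25 because it had no value in wild type replicate 1, read -1.22 ± 0.19 over the other arrays. Trophoblast genes (20 tested, adjusted p 0.239) had 1 higher and 1 lower over the list alone and included Krt8 at 1.18 ± 0.27 and Prl3d1 at -0.47 ± 0.10. Mesoderm genes (19 tested, adjusted p 0.612) included Meox1 at -1.19 ± 0.37 and Hand2 at -0.73 ± 0.21, well above background on 1 and 2 knockout arrays. Germline genes (28 tested, adjusted p 0.945) had 1 lower over the list alone, Mael (-0.83 ± 0.14), with Rpl10l at -0.91 ± 0.25. Imprinted genes (37 tested, adjusted p 0.971) included Kcnq1ot1 at -1.04 ± 0.26 and Peg13 at -0.51 ± 0.14. X inactivation genes (10 tested, adjusted p 0.181) had a median of -0.14, with 2 positive and 8 negative. Their list mean had an exact permutation p of 0.1. So did the means of the trophoblast, SCAN domain, immediate early and heat shock, and homologous recombination and repair lists. Y-linked genes (7 tested, adjusted p 0.945) had 1 higher and 2 lower over the list alone. Among them Sry and Rbmy, not well above background on any knockout array, were at least 1.25-fold and 1.54-fold lower and not called over all probes (adjusted p 0.0818 and 0.120).

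Among genes of stress and metabolism, the immediate early and heat shock list came nearest to the threshold (27 tested, median 0.48, adjusted p 0.0561). Of its members, 2 were higher over the list alone, the transcription factor Junb (1.53 ± 0.28) and Btg2 (0.77 ± 0.16). It passed without wild type replicate 1 (adjusted p 0.00108) or wild type replicate 3 (0.0262), and under quantile normalization (0.0230), the median shift (0.0312), normexp (0.0204), the trended prior (0.0489) and among the brighter probes (0.0346). Wild type replicate 2 stood apart, with a list mean of -0.82 against 0.19 and -0.13 in wild type replicates 1 and 3, and without it the median was 0.26 and the adjusted p 0.245, with an adjusted p of up to 0.709 over the alternatives. Cholesterol synthesis genes (25 tested, adjusted p 0.156) included Insig1 at 0.88 ± 0.18 and Mvk at -0.30 ± 0.11. Genes of the integrated stress and unfolded protein response (34 tested, adjusted p 0.169) included Cebpb at -0.64 ± 0.13 and Ddit4 at 0.96 ± 0.22, and were called lower without a filter (0.0429) and without wild type replicate 3 (0.0262). Their list mean was 0.49 in wild type replicate 1 against -0.18 and -0.14 in replicates 2 and 3. The knockout arrays (0.04, -0.07 and -0.14) lay within that range, and the camera adjusted p ran up to 0.785 over the alternatives. Interferon response genes (32 tested, adjusted p 0.231) included Tap1 at 0.59 ± 0.15 and H2-D1 at 0.44 ± 0.14, with a median of 0.21. They were called higher without wild type replicate 1 (median 0.42, adjusted p 0.00833), and without wild type replicate 2 the median was -0.27 (adjusted p 0.559, up to 0.761 over the alternatives).

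RNA polymerase III, histone, cell cycle and repair genes did not pass in the original setting. RNA polymerase III genes (30 tested) had a median of -0.13 and an adjusted p of 0.0869, with the TATA-binding protein Tbp at -0.32 ± 0.10 and the TFIIIC subunit Gtf3c2 at -0.35 ± 0.12, whose other probe read 0.23. They were called lower without a filter (adjusted p 0.0189), with array weights (0.0165) and without wild type replicate 2 (median -0.19, adjusted p 0.0119, up to 0.709 over the alternatives). Core histones (41 tested, adjusted p 0.169) had 0 members higher and 5 lower when adjusted over the list alone, among them the H2B genes H2bc14 (-0.68 ± 0.11) and H2bc1 (-0.68 ± 0.11). They were called lower without a filter (0.0429) and without wild type replicate 3 (median -0.18 against -0.093, adjusted p 0.0428). Linker histones (8 tested, adjusted p 0.502) included H1f10 at 0.52 ± 0.17 and H1f8 at 0.22 ± 0.12. G1/S and DNA replication genes (38 tested, adjusted p 0.169) included Cdk4 at -0.53 ± 0.13 and Cdc45 at 0.43 ± 0.10. Homologous recombination and repair genes (56 tested, adjusted p 0.239) included Brca1 at 0.51 ± 0.12 and Xpa at -0.54 ± 0.14. SCAN domain zinc finger genes (32 tested, adjusted p 0.471) included Zscan5b itself and Pgbd1 at 0.44 ± 0.10. In 13 of these 22 lists no member passed when adjusted over the list alone. The sign of the median differed from that of the test in 4 lists (endoderm, linker histones, Y-linked and germline genes), and the sign of the mean differed in the germline and imprinted lists. None of the 27 lists passed with an estimated correlation, where the smallest adjusted p was 0.709.

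**Figure D3:**
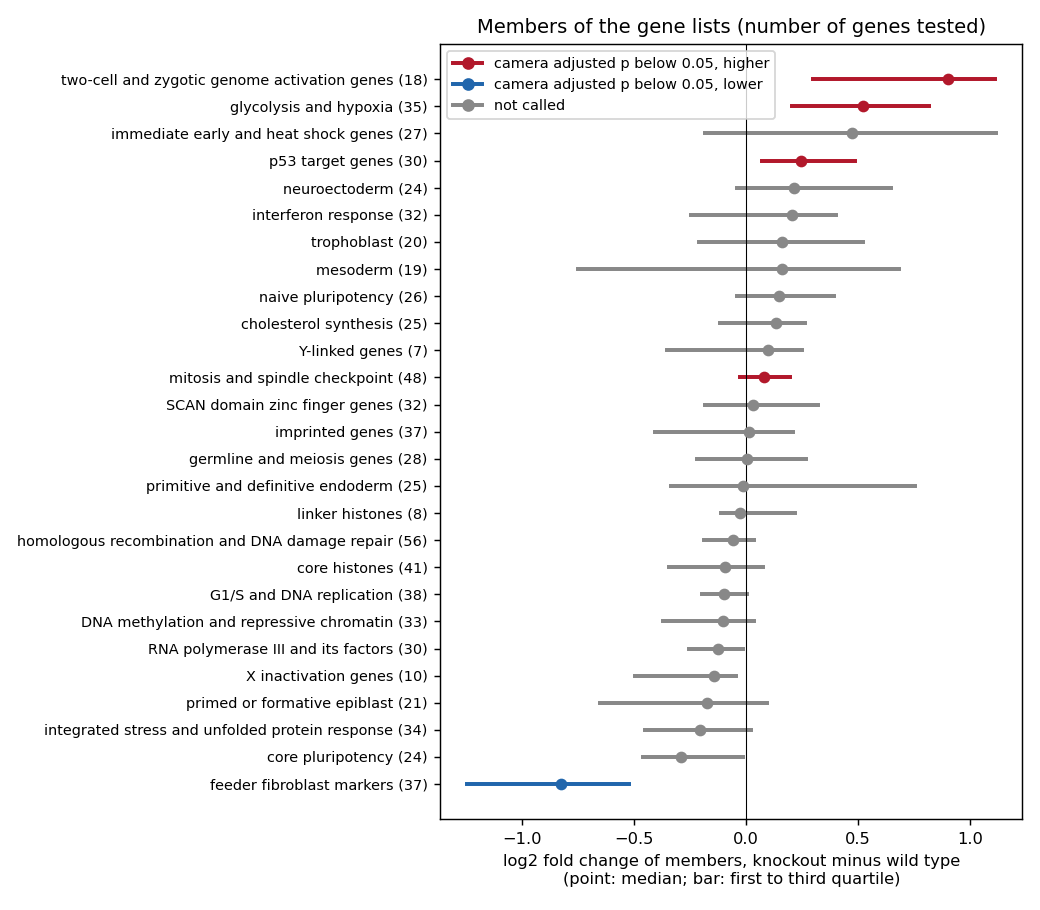
Log2 fold change (knockout minus wild type, horizontal axis) of the members of each of the 27 gene lists, as the median (point) and the interquartile range (bar), with the number of genes tested in brackets. The 4 lists in red and the feeder list in blue (median -0.83) passed the camera test with the preset correlation, and the others in grey did not.

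No chromosome was shifted as a whole. The median log2 fold change of the 20 chromosomes with at least 100 genes lay between -0.07 and 0.01, where 3 copies against 2 would give 0.58. None of the 22 chromosomes passed the camera test (smallest adjusted p 0.562), and 1 had an unadjusted p below 0.05, the mitochondrial chromosome with 7 genes. That chromosome was called without knockout replicate 1 (adjusted p 0.0173), and the smallest chromosome adjusted p ran up to 0.999 over the alternatives.

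Genes near Zscan5b did not pass the test. Within 1 Mb on chromosome 7 there were 36 tested probes for 28 named genes. Of these probes 0 were called higher or lower by limma. An unadjusted p below 0.05 was found for 10 of the 36, against 5836 of all 26651 tested probes. The smallest adjusted p was 0.0972, for the zinc finger gene Zfp418 at -0.57 ± 0.12 (SE). The paternally expressed gene Peg3 read -0.17 ± 0.28 and Aurkc, a kinase of meiotic cells, 0.81 ± 0.22 (both chosen after their values were seen). There was 1 call with array weights, 1 without wild type replicate 1 and 2 without wild type replicate 2.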

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

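The comparison of negative control spots below was chosen after the arrays' summary values were seen. These spots lie outside the probes used for gene expression, and their mean net signal was 28.7 ± 1.04 on the knockout arrays against 23.0 ± 0.33 on the wild type arrays (SD, n = 3 each). All 3 knockout arrays (29.9, 27.9 and 28.2) lay above all 3 wild type arrays (22.7, 22.9 and 23.3), which gives an exact two-sided permutation p of 0.1, the smallest possible. The slides of the genotypes thus differed in the signal of spots that have no target.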

How the results depend on the processing

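Every alternative here was planned except the test on probes with signal above the median, which was chosen after seeing the data. The counts of 33 higher and 91 lower probes became 50 and 131 under quantile normalization, 54 and 177 under the median shift, 33 and 87 with the authors' log2 values, and 434 and 406 with array weights. They were 0 and 0 under normexp, without a filter, with detection on all 6 arrays and with a trended and robust prior. Unadjusted p values below 0.05 then numbered 5785, 6514, 5458 and 6199, and the smallest adjusted p values were 0.0600, 0.0834, 0.0510 and 0.0656. Among the brighter probes there were 8 and 0. At least 2-fold, 18 and 70 passed, and at an adjusted p below 0.01, 0 and 0. Leaving out each array in turn gave 0 to 1409 higher and 0 to 1148 lower. The share of higher calls moved by under 10 percentage points with the scaling (26.6% against 27.6% and 23.4%). The causes were not tested, apart from the change in probes or samples tested.

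List counts (4 higher, 1 lower) became 3 higher and 5 lower without a filter, 2 and 1 with detection on all 6 arrays, 3 and 3 with array weights, and 0 and 0 with an estimated correlation, and ranged from 2 to 6 and from 1 to 4 when an array was left out. Glycolysis (0.43 to 0.65) and p53 targets (0.20 to 0.36) stayed called without any 1 array and lost the call only with an estimated correlation, where their medians are 0.52 and 0.24 by construction, as are -0.83 (feeder), 0.078 (mitosis and spindle checkpoint) and 0.90 (two-cell). The two-cell median was 0.87 under quantile normalization, 0.85 with detection on all 6 arrays and 0.48 with array weights, not called in each, and 0.29 to 1.67 when an array was left out. Mitosis was 0.023 under the median shift and 0.078 without a filter and with detection on all 6 arrays, not called, and 0.053 to 0.10 when an array was left out. The feeder median ranged from -1.34 to -0.55. Zscan5b was called with array weights (-1.58) and ranged from -1.55 to -1.08 when an array was left out. Its neighbours numbered 1 with array weights and 0 to 2 when an array was left out, and shifted chromosomes 0 to 1.

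With the replicate number as a block, 0 probes were higher and 0 lower (5153 at an unadjusted p below 0.05, smallest adjusted p 0.183), and the mitosis list, at a median of 0.078, was not called (adjusted p 0.0511). Same-numbered samples correlated in their deviations by -0.14 to 0.23 and others by -0.32 to 0.21, not every sample correlated best with its own number, and the numbers are not taken to pair the samples. The planned fit with the slide as a block was not run, since each slide held 1 genotype.

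Of 1019 values of the 69 named genes under the alternatives fixed in advance, 803 kept their side of the threshold, 180 lost the call, 36 gained it and 0 changed direction. Most of these genes were not called in the original setting, so most values that kept their side are of genes that stayed uncalled. Only a gene called there could lose its call, so 803 of 1019 does not measure how well the calls held. The 20 genes with the strongest changes kept their calls under the median shift, with array weights and without wild type replicate 1 or 2, 19 of them did under quantile normalization and with the authors' log2 values, and all 20 lost them under normexp (adjusted p 0.0600 to 0.220), without a filter, with the trended prior and without wild type replicate 3 or any 1 knockout array. Signal over background limits the lower genes, since 41 of 91 lower probes have only a bound in the knockout.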

Other observations

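The receptor set, the feeder tests and counts of markers, the core pluripotency comparison, the slide count and the matching on signal and GC content, with and without the detection filter, were chosen after the results were seen. The test of the detection rule, the matching of the glycolysis list on signal, the wider hypoxia list and the splits were set before their results were seen. The wording of the test of genotype on the feeder markers was changed once its values were known: as first worded, the place of wild type replicate 1 among the knockout arrays would have counted against the genotype.

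Chemosensory receptors, which were grouped by name only after the lower genes were known (a first, slightly different set of names gave nearly the same count), made up 22 of the 91 lower probes. Of 203 tested probes for olfactory, vomeronasal, taste, trace amine and formyl peptide receptors, 22 fell and 0 rose by limma, with 83 lower and 8 higher at an unadjusted p below 0.05. Within the dimmest 40% of the tested probes, 22 of 193 receptor probes were lower, against 67 of 10467 others, a count that restates how the set was found and carries no test. Lower calls came from 16 of 160 olfactory, 3 of 33 vomeronasal, 2 of 6 taste, 1 of 2 formyl peptide and 0 of 2 trace amine receptor probes. The median was -0.33, or -0.29 with the 32 probes that had only a bound set at that bound, and it stayed negative under quantile normalization (-0.36), the median shift (-0.38), the authors' log2 values (-0.32) and normexp (-0.12). With detection required on all 6 arrays it was -0.18 over 104 probes, among the 6 receptor probes in the brighter part above the median it was -0.058, and over all 1552 receptor probes without a detection filter it was 0.32. The 22 lower calls became 0 in each of these last 3 settings, under normexp, with the trended prior, with the replicate block, and without wild type replicate 3 or any 1 knockout array. They became 43 with array weights, 28 without wild type replicate 1 and 52 (with 2 higher) without wild type replicate 2. The array means were 0.14, 0.33 and 0.20 in wild type and -0.14, -0.33 and -0.20 in the knockout. They too restate how the set was found, so their exact permutation p of 0.1 carries no test.

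Receptor probes are dim, and 193 of 203 lie in the dimmest 40% of the tested probes, so signal level and probe composition are the first explanations to weigh. The receptor median lay at percentile 0 of 10000 random probe sets matched on mean signal and GC content, whose middle 95% ran from -0.07 to 0.09. That comparison covers a set named from the lower calls and probes kept by the detection rule, and without the rule the median of 1545 receptor probes with a value on all arrays (0.32, percentile 9.08) lay inside the middle 95% of sets matched in the same way (0.318 to 0.329). Of those 1545 probes, 1086 were not well above background on any array, so their median says little about the others, and signal level and GC content stay open. With probes kept by mean signal in place of the detection rule, 195 receptor probes had a median of -0.30 and again lay at percentile 0 (10 lower calls), but 179 of them were the probes tested before, so this test hardly changed the set and the detection rule stays open, although that percentile had been set as the result to exclude it. The spike-ins went both ways on the knockout slide, with the 2 dimmest higher (by 0.11 and 0.32, log2) and the other 8 lower (differences of -0.25 to -0.037), and no slide held both groups (0 slides), so a slide effect cannot be told apart from the genotype. A lower level of receptor transcripts in the knockout is a hypothesis that these arrays leave untested.

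The shift of the glycolysis and hypoxia list may reflect how the cultures were grown, the array slide or the genotype. Fewer feeder cells in the knockout cultures would raise stem cell transcripts alike, but the core pluripotency list had a median of -0.29 with its upper quartile below 0, against 0.52 for glycolysis and hypoxia. The pluripotency list may itself differ between the genotypes, so this comparison does not exclude a feeder effect. Wild type replicate 1 had a feeder mean of -0.53, like the knockout arrays, and a glycolysis and hypoxia mean of -0.20, like the wild type arrays. That is 1 array only. The list median lay at percentile 100 of 10000 random lists matched on mean signal, whose middle 95% ran from -0.16 to 0.01, which argues against a trend with brightness. A further list of 30 hypoxia-inducible genes, none of them in the first, was higher in the 28 measured (camera p = 0.00699, and p = 0.103 with an estimated correlation), with 17 positive and 11 negative, a median of 0.16, 0 called over all probes, and 5 higher and 1 lower when adjusted over the list alone, led by Bhlhe40 at 1.17. Slide and genotype cannot be told apart, with 0 slides holding both groups, and oxygen supply or culture density was not tested.

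For the feeder markers, carry-over of fibroblasts that differs between cultures is a candidate explanation. The list mean ranged over 1.46 among the wild type arrays, more than the difference between the genotypes (-0.81), and wild type replicate 1 (-0.53) lay among the knockout arrays (-0.55 to -0.18), so an effect of the genotype stays open (exact permutation p 0.3). The markers did not move alike. In 23 of 37, wild type replicates 2 and 3 lay above all knockout arrays and replicate 1 did not, as in S100a6 (4.16 in replicate 1 against 5.93 and 6.03, and 4.04 ± 0.23 in the knockout, SD, n = 3). In 6 (Vim, Fstl1, Serpinh1, Ccl2, S100a4 and Cd44) all 3 wild type arrays lay above all knockout arrays, as in Vim (4.32 ± 0.28 and 3.58 ± 0.21). In 1, Ccn1, they lay below (2.63 ± 0.94 and 3.81 ± 0.06), and the other 7 showed none of these orders, among them the brightest, Fn1 (5.79 ± 0.26 and 5.83 ± 0.12), and Ccn2 (3.56 ± 0.71 and 4.15 ± 0.25). The labels name no sort that would remove feeder cells, 1 marker is shared with the mesoderm list and 1 with the imprinted list, and how many of the markers the stem cells themselves express was not measured.

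Among the 10 splits of the 6 arrays, the real one called 124 probes and the highest other 0 (1 split as large). The real split called 5 gene lists and the highest other 10 (8 splits as large), and for chromosomes the values were 0 and 2 (10 splits as large). At an unadjusted p below 0.05 the real split gave 5836 probes, and the split of wild type replicates 1 and 3 with knockout replicate 1 against the others gave 4189, where the remaining splits gave 334 to 1102, which points to a structure among the arrays other than the genotype. The 10 splits are too few for a share under 0.05. The glycolysis and hypoxia list differed by 0.52 in the real split and by at most 0.31 in the others, 5 of which also called it. The other splits do not balance the genotypes, so part of any difference between the genotypes remains in them. Their list calls therefore do not tell whether the shift of this list goes with the genotype.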
